A study of Rattus norvegicus with 10 samples.

How the data were processed

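Gene expression was measured in mammary tumours induced in female Sprague-Dawley rats with a single oral dose of the carcinogen 7,12-dimethylbenz(a)anthracene (DMBA, 100 mg/kg). Per the labels, 5 tumours, chosen as Bloom-Richardson grade II, were each sampled at 2 moments, which gave 10 arrays. The basal sample was a Trucut needle biopsy at 12 weeks of age, when the tumour measured 2 cm3 and no treatment had been given. The final sample came from the same tumour at sacrifice, at 19 weeks of age, after hydroxytyrosol, a phenolic compound of olive oil, had been given by gavage at 0.5 mg/kg on 5 days a week for 6 weeks. The sample labels call the basal piece a breast tumour biopsy and the final piece total breast tumour at sacrifice, which names a needle piece against a whole tumour. The design text calls both pieces Trucut samples, so the sources used here leave open whether the way of sampling differed. Tumours without hydroxytyrosol at the later age were not analysed here. A difference between final and basal samples therefore holds the treatment, the age, the growth of the tumour and the sampling together.

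RNA from the frozen tumours was labelled with biotin and hybridised to Affymetrix rat genome expression arrays, per the labels. The authors normalised the intensities by Robust Multichip Average (RMA), per the design text and the submitters' processing notes; the software version of that step is not given in the sources used here. The deposited values were read as RMA signals on the log2 scale, from their range and the near-equal medians of the arrays, since the labels do not name the scale. The design text describes a filter on control and dim probe sets, but the deposited table still held 57 control probe sets, so the values used here are those before that filter. The authors tested for differences with Student's test for paired samples in the GeneSpring software, per the design text. RMA brings arrays to a common distribution, so a change in the total amount of RNA per cell would not show in these values.

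The table held 31099 probe sets. Of the 31042 that were not controls, the platform annotation of 2016 gave 1 gene symbol to 20826, several to 436 and none to 9780, and no gene was named from a probe set with several symbols. The dimmest 40% of probe sets by mean over the 10 arrays (below 5.15 on the log2 scale) were left out, which kept 18625 probe sets for 10839 genes. No column of values was left unused. The arrays give no read depth, and their number limits the precision.

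Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with statmod 1.5.0 for the random block), with the tumour as a block because the labels give both samples of a tumour the same identifier. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The fit left 4 residual degrees of freedom per probe set and a prior of 2.64. Whether the identifiers pair the arrays was also checked in the values. The deviations of basal and final arrays from their group means, correlated across probe sets, which are not independent replicates, averaged 0.30 over the same-tumour pairs (one-sided exact permutation p = 0.025 over 120 pairings). The correlation was 0.72 in tumour 66D2, 0.47 in 67D3, -0.16 in 45D3, 0.29 in 49I1 and 0.17 in 51I1. In 4 of the 5 tumours the final array matched its own biopsy best. Without the tumour block, 0 probe sets passed the limma threshold, 1001 had an unadjusted p under 0.05 and 11 gene lists passed.

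Before the data were examined, 32 gene lists were fixed. The pathway lists were proliferation, Wnt antagonists, Wnt targets, apoptosis, NRF2 targets, antioxidant enzymes, aryl hydrocarbon receptor targets, p53 targets, oestrogen response, milk secretion, lipogenesis, cholesterol synthesis, hypoxia, immediate-early genes, heat shock, the unfolded protein response, interferon response, MHC class II, inflammation and collagen matrix. The marker lists were for luminal epithelium, myoepithelium and smooth muscle, adipocytes, endothelium, macrophages, T and NK cells, B and plasma cells, mast cells, neutrophils, skeletal muscle, skin keratinocytes and blood. Each list was tested with camera at a preset correlation of 0.01 between genes, on 1 probe set per gene (the brightest), with Benjamini-Hochberg adjustment over the 31 lists that had at least 3 tested members. Camera with an estimated correlation, fry and an exact sign-flip test of the per-tumour medians were alternatives. A few genes stand in more than 1 list, Fas among the p53 targets and the apoptosis genes.

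The rule for naming genes was fixed at the same time. It takes the 10 genes with the smallest p in each direction among those that moved the same way in all 5 tumours where fewer than 5 genes pass the threshold, Sfrp4 and Mki67 whatever their values, and up to 4 members of each list. Which of those up to 4 members are mentioned was chosen after their values were seen. The clock and small proteoglycan lists, and the genes named from the fit without 45D3, were also chosen after values were seen. Sfrp4 was fixed because the study's later publication discusses it.

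The alternatives covered the tumour block, the filter on dim probe sets (none, the dimmest 60%, or below the BioB spike-in), median centring and quantile normalization between arrays, trend and robust settings, array weights, the methods' t-test, 1 probe set per gene, and each tumour left out in turn. After the values were seen, 2 fits were added. The first held as a covariate each array's difference between the 3′ and 5′ control probe sets of hexokinase, a measure of RNA integrity and labelling. The second held the median of the skeletal muscle list. With 5 tumours such a fit estimates the change expected where the covariate did not change. It therefore weighs most the tumours whose covariate changed least. These were 66D2, 49I1 and 51I1 for hexokinase, and 45D3 and 51I1 for the muscle list. Other traits of these tumours cannot be told apart from the covariate.

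The steps were tested on simulated data for the final against basal comparison with 18625 probe sets. Of 50 probe sets changed at each size, the limma step called 10% at a log2 change of 0.5, 78% at 1, 96% at 2 and 100% at 3, with 6 unchanged probe sets among 148 calls. The simulated noise was drawn independently for each probe set, with limma's moderated SD of that probe set taken as the true SD. Moderated SDs vary less between probe sets than unmoderated ones, so these shares may be higher than the real data would give. They do not show that changes of these sizes would have been called in the real data. A list of 20 genes shifted by 0.5 had a camera p of 2.29e-19 from limma's list step, and an unshifted list 0.380. As the simulated genes were independent, this does not test the preset correlation on lists whose members move together.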

Results

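The series profiled 5 DMBA-induced rat mammary tumours, each as a basal biopsy before treatment and as a final sample after 6 weeks of oral hydroxytyrosol, with 5 arrays in each group. The array medians over the tested probe sets were 7.75 ± 0.05 (SD, n = 5) on the log2 scale in basal and 7.77 ± 0.02 (SD, n = 5) in final arrays. GAPDH, the housekeeping control of the study, had a mean signal of 13.01 ± 0.43 (SD, n = 5) in basal and 13.03 ± 0.11 (SD, n = 5) in final arrays. The 3′ minus 5′ difference of the hexokinase control, which grows when RNA is degraded or incompletely labelled, was 1.57 ± 0.59 (SD, n = 5) in basal and 1.02 ± 0.08 (SD, n = 5) in final arrays. It was highest in the basal arrays of 45D3 (2.36) and 67D3 (2.03).

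The study asked how expression in the tumours differed after hydroxytyrosol from that before it. Sfrp4, a secreted antagonist of Wnt signalling, had a mean log2 signal of 5.60 ± 0.42 (SD, n = 5) in biopsies and 8.31 ± 1.41 (SD, n = 5) in final samples, a difference in signal of 2.71 (SE 0.44). All 5 biopsy signals, from 5.15 to 6.04, lay near the dim cutoff of 5.15 and below the BioB spike-in (8.04), so the biopsy level is not shown to be above background and no fold is given. The final signal lay above BioB in 4 tumours and was higher than the biopsy signal in 5 of 5, but in 45D3 both signals, 5.30 and 6.10, lay below BioB. Per2, a repressor in the circadian clock, was 8.54 ± 0.30 (SD, n = 5) in biopsies and 7.47 ± 0.28 (SD, n = 5) in final samples, a log2 difference of -1.07 (SE 0.11), and was lower in 5 of 5 tumours. None of these differences passed the threshold over all genes (limma, adjusted p = 0.413 for both). Adjusted over the list alone, Sfrp4 passed among the Wnt antagonists (limma, adjusted p = 0.00348). Sfrp4 was fixed for reporting because the study's later publication discusses it, so passing within its own list is not independent support.

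Among the other genes that were higher in all 5 final samples with the smallest p were Fas, a death receptor and p53 target (log2 difference 0.70), and Cryab, the small heat shock chaperone alpha B-crystallin (1.02). Pdlim3 and Capn3, which encode proteins of muscle fibres, differed by 1.75 and 1.09, and with the skeletal muscle list as a covariate Pdlim3 differed by 0.93. Abcc8, the sulphonylurea receptor subunit of a potassium channel, differed by 1.18. Olfml2a, Klhdc7a, Tmem150c and Ska2l1 lay between 0.56 and 0.81. Among those lower in all 5 were Jun, a subunit of the AP-1 transcription factor (-0.75), Traf3ip2, an adaptor of interleukin-17 signalling (-0.93), Ccar1, a transcriptional coactivator (-0.88), and Taf1d, a subunit of the RNA polymerase I factor SL1 (-0.85). Hspa2, a member of the HSP70 family, differed by -0.70, Rhebl1, a small GTPase, by -0.73, Kcnj14, a potassium channel whose final mean lay under the dim cutoff, by -0.56 against that cutoff, and the unnamed loci LOC102547700 and LOC100912041 by -0.80 and -0.79. All had an adjusted p of 0.413. Together with Sfrp4 and Per2 these are 20 genes, of which 14 had a group mean below BioB, and 9 had both means below it (Fas, Ska2l1, Klhdc7a, Capn3, Abcc8, Pdlim3, Kcnj14, Rhebl1 and Hspa2), so their values are differences in dim signal and no folds are given. Mki67, the Ki-67 proliferation antigen, differed by -0.32 (SE 0.33, adjusted p = 0.821), with 3 tumours higher and 2 lower, by 0.03 without 67D3, -0.58 without 45D3 and 0.49 with the skeletal muscle covariate.

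**Figure D1:**
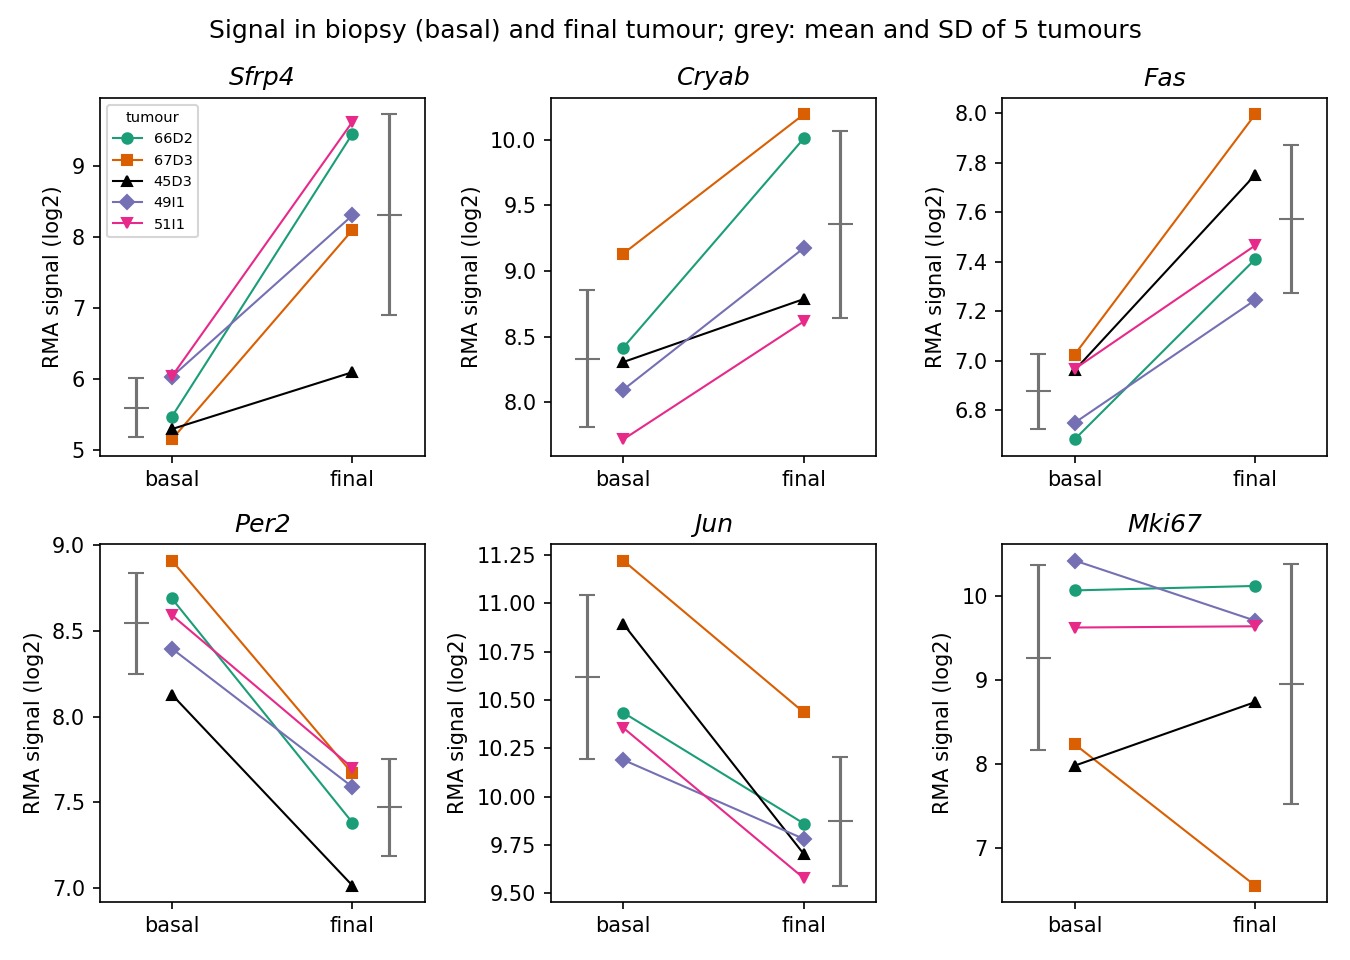
Log2 RMA signal of 6 genes in the basal biopsy and the final sample of each of 5 tumours, joined by a line per tumour, with the group mean and SD in grey. Sfrp4, Cryab and Fas were higher and Per2 and Jun lower in 5 of 5 tumours, while Mki67 was higher in 3 and lower in 2; none passed the threshold over all genes.

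Over the 18625 probe sets, 0 passed limma's adjusted p threshold, the smallest adjusted p being 0.413. At an unadjusted p under 0.05 there were 1494 probe sets, 639 higher and 855 lower, where 931 were expected by chance. The methods' t-test gave 1394 at the same unadjusted threshold and 0 after Benjamini-Hochberg adjustment. In total 1622 probe sets (8.71%) moved the same way in all 5 tumours, 737 upward and 885 downward, against 6.25% for independent symmetric differences. The exact permutation p, one-sided for a larger share, was 0.25 over the splits that part every pair. The 16 such splits allow no p under 0.05. The median SD between tumours was 0.258 in basal and 0.249 in final arrays, a ratio of 0.965 (two-sided exact permutation p = 0.75).

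As groups, 14 of the 31 lists tested passed the camera threshold at the preset correlation, 8 higher and 6 lower in final samples, and none had a median, mean and test of different sign. With an estimated correlation 0 of the 14 held, with fry 0 (smallest adjusted p = 0.707), and the exact sign-flip test with its 32 sign patterns allows no p under 0.05. The immediate-early, collagen matrix, skeletal muscle, proliferation, adipocyte and unfolded protein response lists, 6 in all, passed whichever tumour was left out, and the other 8 did not. With the median of the skeletal muscle list as a covariate, added after the values were seen, 3 of the 14 kept their call: the immediate-early, unfolded protein response and T and NK cell lists. The hexokinase covariate, added likewise, moved several medians outward by over 1.5 times, among them proliferation to -0.64, hypoxia to -0.70, cholesterol synthesis to -0.35, collagen matrix to 1.04, adipocyte markers to 1.14, endothelial markers to 0.84, neutrophil markers to 1.51 and Wnt antagonists to 0.62.

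Immediate-early genes, which are induced within minutes of a stimulus, fell as a list, with a median log2 change of -0.58 and 15 of 15 members lower (camera, adjusted p = 1.20e-07, and adjusted p = 0.748 with an estimated correlation). Ier3 differed by -0.92, Atf3, a stress-induced transcription factor, by -1.34, and Fos, the partner of Jun, by -0.82. Of the 15 members 0 passed over all genes and 3 (Jun, Ier3 and Atf3) passed adjusted over the list alone, with 6 at an unadjusted p under 0.05. The list median was lower in 5 of 5 tumours, most in 45D3 (-1.53) and 67D3 (-0.98), whose hexokinase 3′ minus 5′ difference also fell by 1.47 and 1.02 from basal to final. With that difference as a covariate, added after the values were seen, the list median was -0.02 and the call was lost (adjusted p = 0.481). In that fit Ier3 differed by -0.97, Jun by -0.54, Atf3 by -0.87 and Fos by -0.33, none past the threshold over all genes.

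Proliferation genes of replication and mitosis fell as a list (median -0.35, 32 of 32 members lower, camera adjusted p = 1.90e-05, and adjusted p = 0.748 with an estimated correlation). Mcm7 and Mcm4, subunits of the replicative helicase, differed by -0.36 and -0.48, and Foxm1, a transcription factor of mitotic genes, by -0.38; 0 members passed over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Mcm4 differed by -0.32 without 67D3. The per-tumour median was 0.87 in 45D3 and negative in the other 4, from -0.14 in 66D2 to -1.28 in 67D3. With the skeletal muscle covariate the list was higher (median 0.19, camera adjusted p = 0.0109), while Mcm7 differed by -0.11, Mcm4 by -0.03 and Foxm1 by -0.10. That fit weighs 45D3 and 51I1 most, so 45D3 (0.87) contributes to this reversal, which is not shown to be an effect of muscle.

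The unfolded protein response list fell by 0.25 in the median, with 13 of 14 members lower (camera adjusted p = 8.29e-04, and adjusted p = 0.748 with an estimated correlation). Herpud1, a component of protein disposal at the endoplasmic reticulum, differed by -0.36, and Xbp1 and Atf4, transcription factors of this response, by -0.29 and -0.30, while the chaperone Dnajb9 differed by -0.27. These 4 were the members at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. With the skeletal muscle covariate Xbp1 differed by -0.19. The list's per-tumour median was lower in 4 tumours and 0.06 in 45D3.

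Hypoxia genes fell as a list (median -0.23, 15 of 16 lower, camera adjusted p = 0.0169, and adjusted p = 0.748 with an estimated correlation). Vegfa, the angiogenic growth factor, differed by -0.93, Ndrg1 by -0.75 and Car9, a carbonic anhydrase, by -0.71, with 0 members past the threshold over all genes and 0 adjusted over the list alone. Without 51I1 Ndrg1 differed by -0.44 and Car9 by -0.39, and Car9 differed by -1.26 without 45D3 and by -0.35 with the skeletal muscle covariate. With the hexokinase covariate these 2 differed by -1.22 and -1.44. The hypoxia list's per-tumour median was lower in 4 tumours and higher in 45D3 (0.71). The list did not pass without 66D2 (adjusted p = 0.0588), 49I1 (0.103) or 51I1 (0.132), or with the skeletal muscle covariate (0.487, median -0.16). Cholesterol synthesis genes fell by 0.13 in the median, with 12 of 12 lower (camera adjusted p = 0.0134, and adjusted p = 0.748 with an estimated correlation). Insig1, a sterol-regulated brake on the pathway, differed by -0.39 and the isomerase Idi1 by -0.33, and 0 members passed over all genes or adjusted over the list alone. Idi1 differed by -0.52 without 45D3, by -0.52 with the hexokinase covariate and by -0.07 with the skeletal muscle covariate, where Insig1 differed by -0.21. That call was lost without 66D2 (adjusted p = 0.0749) or 51I1 (0.0937), without the tumour block (0.246), with the tumour as a random block (0.231) and with the skeletal muscle covariate (0.384, median -0.07). In 4 tumours its median was lower and in 45D3 higher (0.31).

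Mast cell markers fell as a list by 0.81 in the median, with 6 of 8 lower (camera adjusted p = 0.0434, and adjusted p = 0.748 with an estimated correlation). The proteases Cpa3 and Mcpt1 both differed by -1.04 and Fcer1a, a chain of the IgE receptor, by -0.97; 0 members passed over all genes or adjusted over the list alone. Tumour 67D3 carried much of these values, and without it Cpa3 differed by -0.50, Mcpt1 by -0.33 and Fcer1a by -0.45. In 3 tumours the mast cell median was lower and in 2 higher. The call was lost without 66D2 (adjusted p = 0.0749), 67D3 (0.111), 45D3 (0.249) or 49I1 (0.0991), without the tumour block (0.362), with the tumour as a random block (0.329), after median centring (0.0749) or quantile normalization (0.0630) and with the hexokinase covariate (0.610, where the median was still -0.65), and with the skeletal muscle covariate the list was higher (median 0.36, adjusted p = 5.53e-04), with Cpa3 at 0.24, Mcpt1 at 0.37 and Fcer1a at 0.35. With the hexokinase covariate Mcpt1 differed by -0.68. The skeletal muscle covariate fit weighs 45D3 and 51I1 most, the 2 tumours whose mast cell median was higher, so its reversal is not shown to be an effect of muscle.

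Among the lists that rose, skeletal muscle markers had the largest median, 2.63, with 9 of 9 members higher (camera adjusted p = 9.44e-07, and adjusted p = 0.748 with an estimated correlation). Acta1, skeletal muscle actin, had a mean of 6.19 ± 2.05 (SD, n = 5) in basal and 10.13 ± 3.43 (SD, n = 5) in final samples. Atp2a1, the calcium pump of fast muscle, differed by 1.94, and by 1.09 without 67D3. Myoglobin (Mb) and fast troponin T (Tnnt3) had biopsy means under the dim cutoff of 5.15, and against that cutoff they differed by at least 2.00 and 1.65. With the 5 members under the cutoff in biopsies set to it, the list median was 1.98. In this list 0 members passed over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05. The median per tumour was 4.34 in 66D2, 6.58 in 67D3, 0.22 in 45D3, 1.60 in 49I1 and 0.19 in 51I1. These values were not held at the dim cutoff. In 66D2 and 49I1 they are those of Ckm, whose biopsy mean (4.22) lay under it, so their size is uncertain. In 51I1 the median is that of Myh1, whose biopsy mean (10.49) was far above those of the other members, so a rise of muscle genes there is not shown.

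Collagen matrix genes rose as a list (median 0.57, 20 of 20 higher, camera adjusted p = 9.44e-07, and adjusted p = 0.748 with an estimated correlation). Postn and Sparc, matrix proteins of fibroblasts, differed by 0.42 and 0.43, and Col6a1 and Col6a2, chains of collagen VI, by 0.50 and 0.61, with 0 members past the threshold over all genes and 0 adjusted over the list alone. Without 45D3 Col6a1 and Col6a2 differed by 0.76 and 0.94, with the hexokinase covariate by 0.87 and 1.07, and with the skeletal muscle covariate by 0.14 and 0.12, where Postn differed by 0.22 and Sparc by 0.12. The median was between 0.61 and 1.13 in 4 tumours and below 0 in 45D3. Adipocyte markers rose by 0.69 in the median with 11 of 11 higher (camera adjusted p = 7.28e-05, and adjusted p = 0.748 with an estimated correlation). The lipid carrier Fabp4 differed by 2.31, Gpd1 by 0.97 and Dgat2, an enzyme of triglyceride synthesis, by 0.50; 0 members passed over all genes or adjusted over the list alone. Gpd1 differed by 0.51 without 51I1 and by 0.48 with the skeletal muscle covariate, and with the hexokinase covariate Fabp4 differed by 3.79 and Dgat2 by 0.26. The adipocyte median was higher in 4 tumours and lower in 45D3 (-0.65). With the skeletal muscle covariate the collagen call was lost as its median went to 0.12 (adjusted p = 0.775), while the adipocyte list narrowly missed the threshold with a median of 0.48 (adjusted p = 0.0528).

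Endothelial markers rose by 0.41 in the median, with 9 of 10 higher (camera adjusted p = 0.00944, and adjusted p = 0.748 with an estimated correlation). Cldn5, a tight junction protein, differed by 0.86 and Vwf by 0.44, and 0 members passed over all genes or adjusted over the list alone. Cldn5 differed by 1.38 without 45D3, 1.53 with the hexokinase covariate and 0.33 with the skeletal muscle covariate, where Vwf differed by 0.28. The endothelial median was higher in 3 tumours and lower in 2, 45D3 (-1.04) and 49I1 (-0.09). The call was lost without 66D2 (adjusted p = 0.0749) or 51I1 (0.312) and with the skeletal muscle covariate (0.253, median 0.21). T and NK cell markers rose by 0.46 with the mean change of 12 of 12 members higher (camera adjusted p = 0.0290, and adjusted p = 0.748 with an estimated correlation), with Prf1, the pore-forming protein of cytotoxic cells, at least 0.49 higher against the dim cutoff and the receptor chain Cd3g at 0.75, and 0 members past either threshold, over all genes or adjusted over the list alone. Cd3g differed by only 0.04 without 66D2, and by 1.40 without 67D3, 1.15 without 45D3, 1.39 with array weights, 2.31 with the hexokinase covariate and 1.52 with the skeletal muscle covariate. Not held at the dim cutoff, Prf1 went from 0.94 to 0.62 without 49I1 and to 1.93 with the hexokinase covariate. By tumour, the T and NK median was higher in 66D2 (1.90), 49I1 (1.26) and 51I1 (1.30) and lower in 67D3 (-1.12) and 45D3 (-1.03). That list was lost without 66D2 (adjusted p = 0.511), 49I1 (0.264) or 51I1 (0.144), with the dimmest 60% left out (0.104) and with the BioB filter (0.214), and its median was 1.82 with the hexokinase covariate and 1.07 with the skeletal muscle covariate. The 3 neutrophil markers tested had a median of 0.79 and rose as a list (camera adjusted p = 0.0169, and adjusted p = 0.748 with an estimated correlation). Among them the calcium-binding proteins S100a8 and S100a9 differed by 0.86 and 0.78, 0 members passed over all genes or adjusted over the list alone, and the call was lost without 49I1 (adjusted p = 0.0601), with no filter on dim probe sets (0.353) and with the skeletal muscle covariate (0.292), although the median in that fit was 0.97. Without 66D2 S100a8 differed by 0.52 and S100a9 by 0.29, against 1.51 and 1.62 with the hexokinase covariate, and S100a9 differed by 1.21 with array weights. The neutrophil list's per-tumour median was higher in 4 tumours and lower in 45D3 (-0.11). All 3 of its members had both group means below BioB (8.04), so these are differences in dim signal. With the dimmest 60% left out or the BioB filter the list had too few members to be tested.

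Wnt antagonists rose as a list, with a median of 0.17 and 5 of 6 members higher (camera adjusted p = 0.0434, and adjusted p = 0.748 with an estimated correlation). Beside Sfrp4, Sfrp2 differed by 1.28 and Sfrp1 by 0.27, while Frzb differed by -0.57. Over all genes 0 members passed, and 1 passed adjusted over the list alone. That was Sfrp4, fixed because the study's later publication discusses it. The value of Frzb rests on 45D3, being -0.07 without it, and was -1.03 without 51I1, -0.29 with array weights, 0.02 with the hexokinase covariate and -0.86 with the skeletal muscle covariate. Sfrp1 differed by 0.18 without 66D2, and with the hexokinase covariate Sfrp1 differed by 0.50 and Sfrp2 by 2.58. This list's median was higher in 4 tumours and lower in 45D3 (-0.76). The call was lost without 66D2 (adjusted p = 0.132), 49I1 (0.103) or 51I1 (0.231) and with the skeletal muscle covariate (0.130), although the median in that fit was 0.28. The p53 targets rose by 0.18 in the median with 7 of 10 higher (camera adjusted p = 0.0434, and adjusted p = 0.748 with an estimated correlation). Fas passed adjusted over the list alone, 1 member against 0 over all genes, and the growth arrest gene Gadd45a differed by 0.29 and Ccng1 by 0.26. Ccng1 differed by 0.14 without 45D3 and 0.05 with the hexokinase covariate, and Gadd45a by 0.12 with that covariate and 0.15 with the skeletal muscle covariate. The p53 median was higher in 3 tumours and lower in 2. That call was lost without 67D3 (adjusted p = 0.111), 45D3 (0.668) or 49I1 (0.103), without the tumour block (0.0924), with the skeletal muscle covariate (0.164, median 0.11) and with the hexokinase covariate, where the median was -0.10 (0.766).

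**Figure D2:**
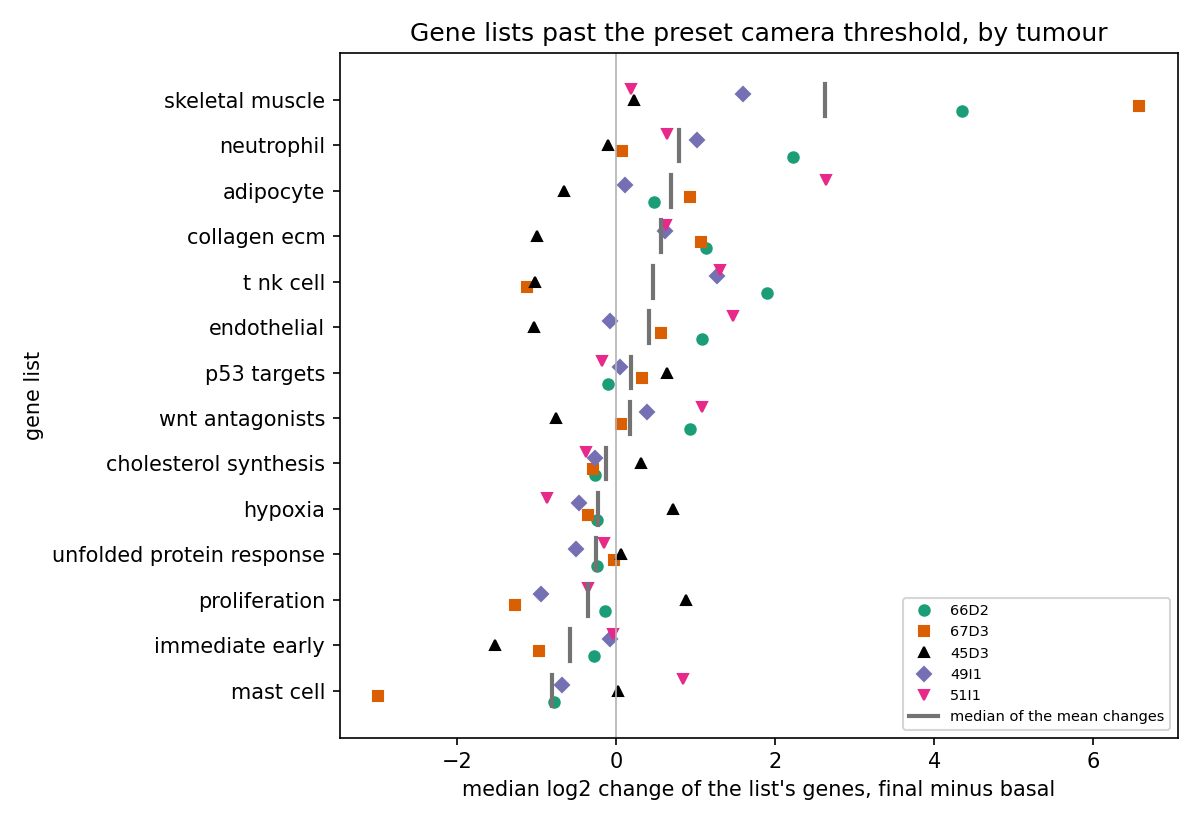
Median log2 change, final minus basal, of each of the 14 gene lists past the preset camera threshold, with 1 point per tumour and a grey bar at the median of the members' mean changes. The immediate-early list was below 0 and the skeletal muscle list above 0 in 5 of 5 tumours. The muscle medians of 45D3 (0.22) and 51I1 (0.19) were small. Tumour 45D3 lay on the other side of 0 from the grey bar in the proliferation (0.87) and endothelial (-1.04) lists, among others.

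The other lists did not pass in the fit of all 5 tumours. Inflammation genes had a median of -0.18 (adjusted p = 0.163), with 0 members past the threshold over all genes and 1, the neutrophil-attracting chemokine Cxcl1 (-1.13), adjusted over the list alone; Il1b, a cytokine, differed by -0.88, by -0.54 without 67D3, by -0.30 with the hexokinase covariate and by -0.31 with the skeletal muscle covariate. Oestrogen response genes had a median of -0.42 (adjusted p = 0.287), with the growth factor Areg at -0.53 (-0.83 with the hexokinase covariate) and the progesterone receptor Pgr at -0.50 (-0.29 without 51I1). Apoptosis genes had a median of 0.04 (adjusted p = 0.210), where Fas was the 1 member past the threshold adjusted over the list alone. NRF2 targets, which hydroxytyrosol has been reported to induce in other systems, had a median of 0.03 (adjusted p = 0.730), with Gclc, an enzyme of glutathione synthesis, at -0.41 (-0.64 without 45D3, -0.77 with the hexokinase covariate and -0.21 with the skeletal muscle covariate), and antioxidant enzymes 0.03 (adjusted p = 0.365). Targets of the aryl hydrocarbon receptor, which DMBA activates, had a median of 0.03 over 3 members and a camera direction downward (adjusted p = 0.730).

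Milk secretion genes had a median of -0.07 (adjusted p = 0.674), with the secretory mucin Glycam1 at -1.85 (-1.06 without 49I1 and -3.21 with the hexokinase covariate), and luminal epithelial markers 0.06 (adjusted p = 0.474), with the epithelial transcription factor Ehf at 0.56 (0.29 with the hexokinase covariate and 0.36 with the skeletal muscle covariate). The median was -0.09 for myoepithelial and smooth muscle markers (adjusted p = 0.344), -0.15 for heat shock genes (0.287), 0.03 for lipogenesis (0.617), 0.07 for the interferon response (0.617) and -0.00 for Wnt targets (0.804). For cell markers it was 0.32 for blood (adjusted p = 0.138), 0.12 for skin keratinocytes (0.617), -0.03 for MHC class II (0.935) and -0.00 for macrophages (0.935). Outside the counts just given, 0 members of these lists passed over all genes or adjusted over the list alone. Only 2 members of the B and plasma cell list, Jchain and Blnk, were tested, so that list was not tested as a group.

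Tumour 45D3 moved apart from the others. Its log2 changes correlated across genes, which are not independent replicates, at -0.19 with those of 66D2, 0.02 with 67D3, -0.43 with 49I1 and -0.27 with 51I1. Without 45D3, 0 probe sets passed limma's threshold, with 3383 at an unadjusted p under 0.05, and 54 had an adjusted p under 0.10, 45 of them higher. Of those 45, 37 were lower in 45D3, but of the 9 that were lower only 1 was higher in 45D3. The 37 included genes of connective tissue matrix, chosen here after their values were seen. Among these were Ogn, a small proteoglycan that differed by 3.39 without 45D3 and by -2.17 in 45D3, and Dpt, a dermal matrix protein (2.95 and -2.67).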

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

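The tests below of RNA integrity, exchanged labels, scaling and handling, with the comparisons against reassigned control differences, were chosen only after the results were seen.

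A sample counted as standing apart where its gap to the nearest other sample exceeded Dixon's critical value for 5 samples, which chance does in about 1 of 20 groups. Of 116 groups of arrays looked at, 7 met this, where chance gives 5.8. Klhdc7a was 5.56 in the final sample of 66D2, against 6.83 to 7.01 in the others. Rhebl1 was 5.48 in the final sample of 51I1, against 5.73 to 5.79. The median level of the Wnt antagonists was 7.34 in the final sample of 45D3 (others 8.34 to 8.70) and that of the collagen matrix list 9.54 in the same sample (others 11.26 to 11.76). The oestrogen response list stood at 8.67 in the biopsy of 66D2 (others 9.67 to 9.90). In the final sample of 67D3 the cholesterol synthesis list stood at 7.94 (others 8.73 to 9.02) and the interferon response list at 8.24 (others 9.16 to 9.42).

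The first pattern is that 45D3 moved against the other tumours: of 1049 probe sets at p under 0.01 in the other 4, 24.2% had the same sign in 45D3. The same share, from fits that include 45D3, was 47.5% of 446 in 49I1, 86.2% in 66D2, 90.4% in 67D3 and 83.6% in 51I1. Degraded RNA in its biopsy stays open: that array had the largest 3′ minus 5′ difference on 3 of 3 control transcripts, and a fit of the other 4 tumours with the hexokinase difference gave the right sign for 54.3% of 659 probe sets, above a bound of 50% that was set before this share was computed but after the control differences had been seen. A comparison added after that share was seen makes it undecided, since 5 of the 24 assignments of the differences to tumours, the true one included, gave as large a share. The highest other was 61.2%. Exchanged labels within the pair stay open too, as 10 of the 12 lists called without 45D3 had the opposite sign in it, while the immediate-early and skeletal muscle lists, 2 in all, had the same sign. Probe sets at an adjusted p under 0.10 in limma without 45D3 were mixed as well. Of the 45 higher, 37 were lower in 45D3, but of the 9 lower only 1 was higher in it. A biopsy rich in connective tissue was met for 1 of the 3 lists of collagen, adipocyte and endothelial genes, which decides neither way. The collagen level of the 45D3 biopsy (10.57) lay within that of the other biopsies (9.93 to 11.22). Its final sample was the lowest final sample on all 3 lists (collagen 9.54, adipocyte 6.72, endothelial 7.24). For these lists the final sample thus stood apart too, and why was not tested. A true difference in how this tumour responded or aged was not tested either.

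The second pattern is the rise of the skeletal muscle list. Further scaling between arrays left the rise in place. The median change was at least 2.61 after median centring and quantile normalization, and the call held in both. This argues only against a difference in scale left between the deposited arrays. RMA had already given them near-equal medians, so these steps could change little and do not test the scaling applied before. Skeletal muscle tissue in the final pieces may account for the rise. A second muscle list of 24 genes was written before its values were seen, and 11 were tested. The dim filter kept genes dim in biopsies only where final arrays were brighter. Of the 11, 8 (72.7%) had a mean log2 change above 1. This lies between the bounds of 80% and 50% set for and against, so the test leaves it open. Des (0.924), Tnni1 (0.940) and Ldb3 (0.999) lay just under 1. By tumour the list's median change was 2.51 in 66D2, 4.59 in 67D3 and 1.46 in 49I1, but 0.08 in 45D3 and 0.002 in 51I1. The rise thus lay in 66D2, 67D3 and 49I1, which the bound on the mean does not show. The troponin Tnnc2 and the myosin light chain Myl1 of that list, picked after their values were seen, differed by 8.11 and 9.14 in 67D3 and by 0.21 and 0.34 in 51I1. The highest signal of the final 67D3 array was 14.11, so both biopsy signals there lay below BioB (7.87). The values in 67D3 are therefore differences in signal from a level not shown to be above background. Treatment and age are confounded with the sampling of the final piece and stay open, untested.

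The third pattern is the fall of the immediate-early list. RNA quality is a candidate explanation: with the hexokinase difference as a covariate the list median went from -0.58 to -0.017, with a spread of 0.43 (SD) between members in both fits, so the call ended because the change itself shrank (adjusted p = 0.481). Of 120 assignments of the differences to tumours, a comparison added after that median was seen, 2 gave a median as high, the true one included. However, Ier3 (-0.92 before, -0.97 after) and Jun (-0.75 and -0.54) kept most of their difference, so RNA quality would leave these members unexplained. Both the covariate fit and the assignments rest on 45D3 and 67D3, which had the largest falls of the list median and of the hexokinase difference. Another trait of these 2 tumours would give the same values, so RNA quality was not tested apart from it. Handling or the hour of the day at sampling cannot be told apart from treatment and age, since no hour is given in the labels used here: a list of circadian clock genes, chosen because Per2 had been seen, was lower as well (camera adjusted p = 0.00327, or 0.0261 without Per2, and adjusted p = 0.730 with an estimated correlation), which partly restates what prompted it and decides nothing. An effect of hydroxytyrosol or of age was not tested separately from these.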

How the results depend on the processing

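The 2 fits with a covariate (hexokinase control difference, skeletal muscle list) were chosen only after the results were seen. The limma count of 0 probe sets held under the block, filter, scaling and left-out-tumour settings and with array weights, against 1494 at an unadjusted p under 0.05, 1394 by the methods' t-test unadjusted (1077 with a gene symbol) and 2 with the hexokinase covariate, of which 1 (Ccn3, 2.44, adjusted p = 0.0237) has a symbol. Sfrp4, which the BioB filter leaves out, kept its direction in the other 17 settings, from 2.32 to 3.49 (adjusted p at least 0.0970, reached without 45D3). Of 1240 values of 72 other genes in the text under alternatives, 7 changed sign, and of 2405 values of the 139 genes the rule takes, 66 did. Those 7 were Mki67 (-0.58 to 0.027 with a tumour left out, and 0.49 with the muscle covariate), Frzb (0.022 with the hexokinase covariate) and, with the muscle covariate, Mcpt1 (0.37), Cpa3 (0.24), Fcer1a (0.35) and Atp2a1 (-0.17). Of those 72 genes, 24 moved by over 1.5 times or turned with 1 tumour left out, 28 with the hexokinase covariate, 32 with the muscle covariate, 3 with array weights and 0 in the other settings. The number of lists called was 14, between 8 and 14 with a tumour left out, 11 without the tumour block, 12 with the tumour as a random block, 10 without a filter on dim probe sets, 7 with the BioB filter (12 of the 14 lists had a value), 8 with the muscle covariate, and 0 with camera's estimated correlation, 0 with fry, 0 with fry's mixed test and 0 with the sign-flip test. With the muscle covariate, proliferation (adjusted p = 0.0109), mast cells (5.53e-04) and MHC class II (0.00158) were higher, heat shock was lower (0.00238), macrophages were higher (0.0141), and the skeletal muscle list itself had 0.752, as its own median was removed. With the hexokinase covariate, p53 targets turned (0.766), heat shock was lower (0.00102), and macrophages (0.00113) and MHC class II (0.00378) were higher. With the tumour as a random block the cholesterol synthesis (0.231) and mast cell (0.329) calls were lost, as was that of mast cells after median centring (0.0749) and quantile normalization (0.0630). With no filter on dim probe sets the Wnt antagonist (0.160), p53 target (0.0859), mast cell (0.0503) and neutrophil (0.353) calls were lost, with the dimmest 60% left out that of T and NK cells (0.104), and with the BioB filter those of hypoxia (0.0591), endothelium (0.0591), p53 targets (0.109), mast cells (0.109) and T and NK cells (0.214). With a tumour left out, the camera adjusted p of MHC class II ran from 0.00556 to 0.778 and that of macrophages from 0.0322 to 0.660. Other lists not called in the main fit passed as well. These were heat shock without 67D3 (0.00635), and blood (0.00828), luminal epithelium (0.0190) and milk secretion (0.0306) without 51I1. Without 49I1 they were inflammation (0.0428), myoepithelium and smooth muscle (0.0428) and apoptosis (0.0482). Removing the tumour block ended the calls of cholesterol synthesis, p53 targets and mast cells and changed no other call. The same-tumour correlation ran from 0.14 (without 66D2) to 0.46 (without 45D3), and the ratio of spreads from 0.862 (without 67D3) to 1.02 (without 66D2). Beyond the covariates and the tests' own constructions, the cause was not tested. Signals near background limit the dim genes: 25.0% of probe sets in basal and 27.8% in final arrays lay above the BioB spike-in.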

Other observations

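The clock and small proteoglycan lists and the count of splits for the unadjusted p were chosen only after the results were seen.

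Genes of the circadian clock were lower together in final samples. Over 15 tested genes the median log2 change was -0.28, with 12 lower and 3 higher, and the list median was lower in 5 of 5 tumours (camera adjusted p = 0.00327, and adjusted p = 0.730 with an estimated correlation). The list was chosen because Per2 had been seen; without Per2 the median was -0.27, with 11 of 14 lower (camera adjusted p = 0.0261, and adjusted p = 0.730 with an estimated correlation). Beside Per2, its fellow repressors Per1 and Per3 differed by -0.72 and -1.17, each lower in 5 of 5 tumours, while Bmal1, an activator whose messenger RNA peaks opposite to theirs, differed by 0.56 and was higher in 4 of 5. With the hexokinase covariate Per2 differed by -1.03, Per1 by -0.53, Per3 by -0.62 and Bmal1 by 0.60, and with the skeletal muscle covariate Bmal1 differed by 0.15. None passed over all genes (limma, adjusted p = 0.413 for Per1 and Per2, 0.548 for Per3 and 0.592 for Bmal1). A shift in the hour at which the pieces were taken could give this pattern, and the value of 0.00327 does not separate it from treatment or age.

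Small leucine-rich proteoglycans, which bind collagen fibrils, were higher together, with a median of 0.62 and 8 of 8 higher (camera adjusted p = 9.77e-04, and adjusted p = 0.730 with an estimated correlation). Ogn differed by 2.28 (SE 0.92) and Aspn, whose biopsy mean lay under the dim cutoff, by at least 1.78, neither past the threshold (limma, adjusted p = 0.614 and 0.605). Ogn differed by 4.03 with the hexokinase covariate and by 1.35 with the skeletal muscle covariate. The list median was 1.41 in 66D2, 0.70 in 67D3, -1.33 in 45D3, 1.13 in 49I1 and 1.56 in 51I1. This list shares Dcn and Lum with the collagen matrix list, so it is not independent of it. As it was chosen after values were seen, its camera p partly restates them, and no value without Ogn and Aspn was computed.

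Other splits of the same arrays were fitted in the same way. The 16 splits that part every pair are too few for a share under 0.05. Among them 3, the real one included, gave as many probe sets at an unadjusted p under 0.05 as the real 1494. The highest other was 3648, when the labels of 45D3 were exchanged. As many lists as the real 14 came in 5 of the 16, the real one included, the highest other giving 16. Every split called lists, the fewest being 5, so the preset threshold called lists whatever the labels. A share of probe sets moving the same way as large as 8.71% came in 4 of the 16, the real one included, the highest other being 19.4%. Without the tumour block, 29 of 100 splits drawn from 126, the real one included, gave as many probe sets as the real 1001, the highest other giving 5665 (1219 at limma's adjusted threshold). That share says nothing of chance for a change within tumours, as 86 of the 100, the highest among them, keep both samples of some tumour on 1 side and so hold differences between tumours. Among the 14 that part every pair the highest other gave 976, and 14 are too few for a share under 0.05.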
